A study of Mus musculus with 7 samples.

How the data were processed

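Total RNA from snap-frozen gastric corpus was labelled as biotinylated cDNA with the Affymetrix WT Plus kit and measured on 1 single-channel array per sample. The deposited table holds log2 signal for 41345 probe sets on 7 arrays, made by the authors with RMA (background correction, quantile normalisation and summary of probes) in Partek, per the submitters' processing notes; the versions of both are not given in the sources used here. The values ran over the range of log2 signal, with array medians from 4.56 to 4.71, and were used as deposited with no further scaling. All 7 columns were used, and the columns of samples not used number 0. Array signal has no read depth, and the number of arrays limits the precision.

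Samples were grouped by the labels: 1 control, 1 array at 24 h, 1 at 36 h, 2 at 48 h and 2 at 72 h. The design text calls the 48 h and 72 h samples independent and says nothing more about which animals they came from. The p-values of single genes therefore measure only the spread between these arrays. The 72 h titles also carry the letters A and B, whose meaning is not given. Replicate numbers are shared by label only and were not used to pair arrays: the differences within the 48 h and 72 h pairs had a correlation of -0.13 across genes, which are not independent replicates.

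Probe sets were joined to genes by the platform's annotation: 23521 had 1 gene, 1814 had several and 16010 had none. Probe sets with 1 gene were kept, and the probe set with the highest mean was used where a gene had more than 1 (1082 genes), which left 22180 genes. Gene names were matched by Entrez identifier to the gene table of the mouse assembly GRCm38.p6 for 23328 probe sets, with 193 not found and 0 symbols changed; that table served for names and gene order only, since the build behind the array is not stated, and no coordinates are given.

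Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with a mean per group and all 7 arrays, for 48 h against control, 72 h against control and 72 h against 48 h. The fit had 2 residual degrees of freedom, from the 48 h and 72 h pairs, and 1.15 prior degrees of freedom; the lone control array is assumed to vary like those pairs. A slope per 24 h was fitted over the 6 toxin arrays with 4 residual and 1.83 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 24 h and 36 h arrays were compared with the control array by counting differences of at least 2-fold, beside the same count within the pairs. RMA left equal values on both arrays of a pair in 2485 genes (11.2%) at 48 h and 2367 (10.7%) at 72 h, and 8813 genes (39.7%) had 7 distinct values over the 7 arrays.

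Gene lists covered the cell types of the stomach, neighbouring tissues, immune and stromal cells, proliferation, energy and sterol metabolism, stress and signalling pathways, the circadian clock, ribosomal proteins and sex-linked genes. Of 43 lists 41 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry; p-values were adjusted over the 41 lists. The 2 lists of sex-linked genes were too short and are given as values. The glycolysis list held Pigq, a gene of GPI anchor synthesis and not of glycolysis, in every comparison. Camera compares a list with all other genes, and fry asks whether a list's genes move on balance in 1 direction. At the preset correlation camera takes genes as nearly independent, so its p-values do not measure how a list varied between arrays. With an estimated correlation it rests on the residual degrees of freedom, 2 in the group fit and 4 in the trend. Few lists could then pass, and a lack of calls there decides little. At 24 h and 36 h each list's median was set against 10000 random lists of the same size and similar mean expression, with bounds that leave 2.5 percent on either side.

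Genes are named by a rule: measured anchor genes of each cell type; the 5 genes with the largest difference in each direction of a tested comparison whose arrays did not overlap, given as values since none was called; the 12 largest in each direction at 24 h and 36 h among genes above the array's median; and up to 4 members per list. Predicted genes, small RNA, mitochondrial, immunoglobulin, T cell receptor, olfactory, vomeronasal and taste receptor genes and pseudogenes were left unnamed: 2 at 72 h against 48 h, 2 in the trend and 1 at 36 h. The comparisons, tests, gene lists and this rule were fixed before the data were examined. Other genes that carry values were chosen after their values were seen: several of those among the other observations, and the genes with a constant difference from the control. Of 468 genes in the table of named genes, 33 had several probe sets and 10 had a probe set of opposite sign at 48 h.

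The pipeline was tested on simulated data with 22180 genes and 50 changed genes per size. At a log2 change of 2 it recovered 56% at 48 h against control, 68% at 72 h against control, 78% at 72 h against 48 h and 90% in the trend. At a log2 change of 1 it recovered 8%, 28%, 36% and 94%. In the trend these sizes were slopes per 24 h, and elsewhere differences between groups, so the trend's percentages are not comparable with the others. Of unchanged genes 4.82%, 4.96%, 5.17% and 4.82% had an unadjusted p under 0.05, and of 10 shifted and 10 unshifted lists 10 and 0 were called. Simulated genes were drawn independently, without equal values, and the lists were random genes. The simulation therefore cannot show how often camera calls lists of correlated genes.

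Alternatives were quantile normalisation again, subtraction of array medians, a filter on dim genes, the mean of a gene's probe sets, all probe sets, eBayes with trend and robust options, the compared groups alone, replicate number as a block, time as rank or log2 hours, and leaving out each array. Added after seeing the data were genes with at least 6 distinct values, crossed replicate numbers, genes outside chromosomes X and Y, fry, the 24 h array alone, the list trend without the 24 h or the 36 h array, and the scalings of the list medians at 24 h and 36 h. Probe sets with several genes or none were left out of the tests because their signal cannot be assigned to 1 gene.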

Results

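Gene expression was measured on single-channel arrays in the gastric corpus, the acid-secreting region of the stomach, of Atp4b-DTR mice aged 8 to 12 weeks. These transgenic mice carry a diphtheria toxin receptor in parietal cells, the cells that secrete acid, so that diphtheria toxin removes them. The mice received 225 ng of toxin per mouse on 3 consecutive days, or saline, and tissue was collected 24, 36, 48 or 72 h after the last dose. The series comprised 7 arrays in 5 groups, with 1 saline control, 1 array at 24 h, 1 at 36 h, 2 at 48 h and 2 at 72 h. The study was designed to follow the corpus through loss of parietal cells and its recovery. After collapsing to 1 probe set per gene, 22180 genes were compared. Values are log2 differences from the control array unless stated otherwise, with the standard error of the limma fit after the sign ±. The number of arrays limits the precision: the control, 24 h and 36 h groups have no replicate, and a trait of the lone control array enters every difference from it.

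The arrays fell into 2 sex patterns that did not follow treatment. Xist, the RNA that silences 1 X chromosome in female cells, had a log2 value of 8.13 on the control and 9.17 on the 24 h array, against 2.70 to 3.27 on the other 5 arrays. The Y-linked gene Eif2s3y had log2 values of 3.81 and 3.40 on the control and 24 h arrays and of 7.79 to 8.39 on the others. Comparisons of 36, 48 and 72 h with the control therefore also compare these patterns, whereas the 24 h array shared the pattern of the control. Array medians also differed slightly: subtracting them shifted the median gene by -0.08 at 24 h, -0.10 at 36 h, -0.10 and -0.14 at 48 h and -0.06 and -0.04 at 72 h, and list medians of similar size moved by over 1.5 times.

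Parietal cell markers were checked first, since the toxin is aimed at cells that express Atp4b. Atp4b, the beta subunit of the gastric proton pump, had a log2 value of 12.94 on the control array, 10.68 at 24 h and 12.33 at 36 h. At 48 h it was 11.66 and 12.39 on the 2 arrays, and at 72 h it was 12.65 and 12.92. Atp4a, the catalytic subunit of the pump, was -1.41 from the control at 24 h, -0.59 at 36 h, -1.25 and -0.42 at 48 h, and -0.36 and -0.15 at 72 h. The median of 27 measured parietal cell genes was -1.27 at 24 h, -0.62 at 36 h, -1.20 and -0.72 at 48 h, and -0.52 and -0.25 at 72 h. The 36 h array thus lay closer to the control than the 24 h array and the first 48 h array. The 2 arrays of 48 h differed from each other in Atp4b more than the 2 arrays of 72 h did.

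**Figure D1:**
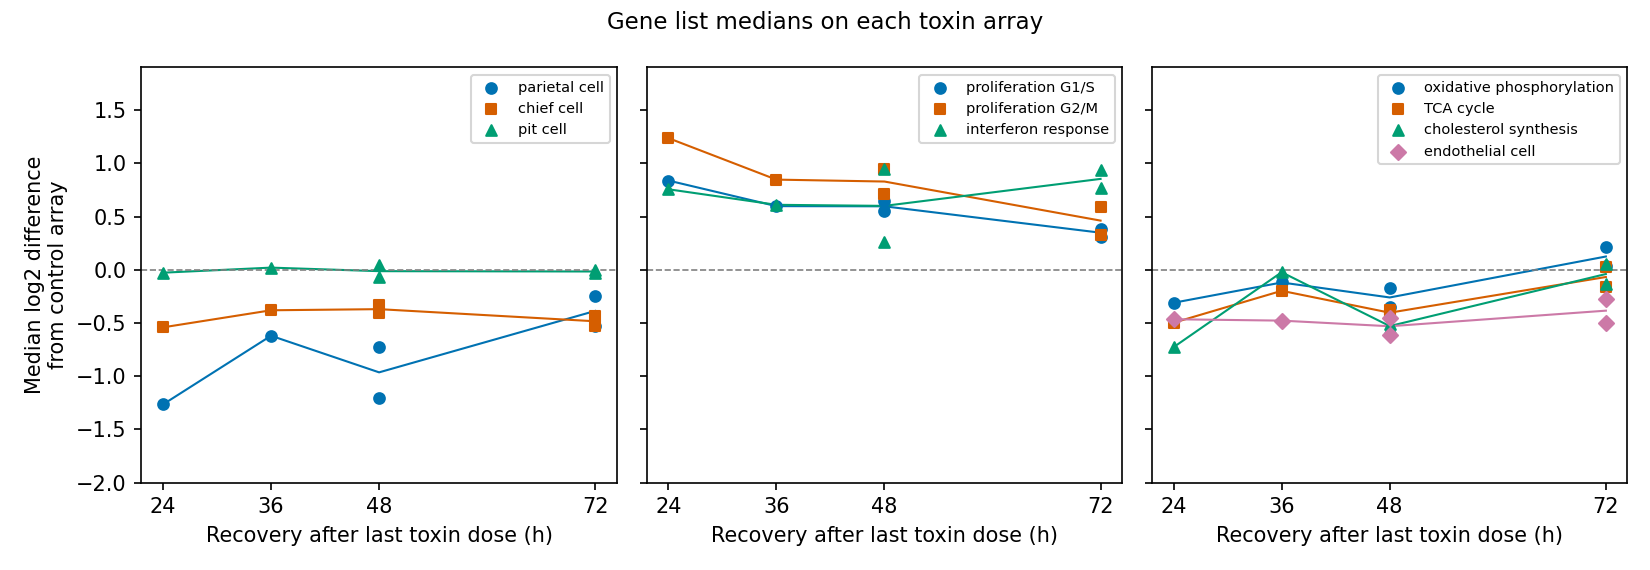
Median log2 difference from the control array of gene lists (y axis) against hours after the last toxin dose (x axis); points are single arrays and lines join the mean at each time. The parietal cell list ran from -1.27 on the 24 h array to -0.52 and -0.25 on the 72 h arrays, while the G2/M list ran from 1.24 to 0.59 and 0.33.

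At 24 h, genes of cell division were higher and genes of parietal cells, mitochondria and sterol synthesis were lower than on the control array. All 42 measured genes of G2 phase and mitosis were higher, with a median of 1.24, and all 37 genes of G1/S transition and DNA replication were higher, with a median of 0.84. The proliferation marker Mki67 was 1.94 above the control, the chromatin remodeller Hells 2.71 and Rrm2, a subunit of ribonucleotide reductase, 2.16. Interferon response genes were higher in 37 of 39 cases, with a median of 0.76, and included Ifit1 at 2.77 and Oasl2 at 2.24. Ribosomal protein genes had a median of 0.37, immediate early genes 0.30 and genes of acute epithelial inflammation 0.17, which became 0.08 with quantile normalisation again and 0.09 with array medians subtracted.

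Of the 27 parietal cell genes, 23 were lower at 24 h. The chloride and bicarbonate transporter gene Slc26a7 was -3.72 from the control and the water channel gene Aqp4 was -3.08. Gpr155 was -3.87 on the probe set used, and -1.36 as the mean of its probe sets. All 21 genes of the TCA cycle were lower, with a median of -0.50, and 57 of 64 genes of oxidative phosphorylation were lower, with a median of -0.31. Cholesterol synthesis genes had a median of -0.73, chief cell genes -0.54 and endothelial genes -0.47. The lowest named genes were B4galnt2, a glycosyltransferase gene, at -5.54, and Rnase1, a secreted ribonuclease gene, at -4.51, and the highest were Dmbt1, a mucosal glycoprotein gene, at 3.41 and Pigr, the transporter of polymeric immunoglobulin, at 3.02. No test was made of 1 array against 1: 267 genes were higher and 371 lower by at least 2-fold, against 107 genes that differed this much between the 2 arrays of 48 h and 71 between those of 72 h. Of 41 lists, 9 lay above and 10 below the bounds set by 10000 random lists matched on size and mean expression.

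At 36 h, cell division and interferon genes were again higher, while the TCA cycle, oxidative phosphorylation and cholesterol synthesis lists lay nearer to the control than at 24 h. The G2/M list had a median of 0.85, the G1/S list 0.60, the interferon list 0.61 and the ribosomal protein list 0.47. The parietal cell list was at -0.62, with Slc26a7 at -4.03 and Gpr155 at -3.62 on its probe set used, or -1.37 as the mean of its probe sets. The TCA cycle list was at -0.20, oxidative phosphorylation at -0.12 and cholesterol synthesis at -0.02, whereas fatty acid oxidation was at -0.25, against -0.22 at 24 h. With array medians subtracted, the TCA cycle was at -0.30, oxidative phosphorylation at -0.22 and cholesterol synthesis at -0.12 at 36 h. Chief cell genes had a median of -0.38, with Cblif, the gene of gastric intrinsic factor, at -1.84. Unfolded protein response genes were at -0.51 and heat shock genes at -0.46 on this array, against -0.20 and 0.16 at 24 h. Mucous neck cell genes were at 0.38.

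The genes furthest above the control at 36 h included Fcgbp and Zg16, both products of mucus-secreting cells, each at 4.93. The chitinase-like gene Chil4 was at 3.99 and Clca1, another secreted product of mucous cells, at 3.85. Lower genes included B4galnt2 at -5.91, the hepcidin gene Hamp2 at -5.15 and Lpl, lipoprotein lipase, at -3.31. The Y-linked genes Eif2s3y, Uty and Kdm5d were at 4.57, 4.15 and 3.42 and Xist at -4.91. In all, 207 genes were higher and 356 lower by at least 2-fold, or 157 and 457 with each array's median subtracted. Among the 41 lists, 10 lay above and 10 below the bounds of the random lists.

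The comparison of 48 h with the control asked how the corpus differed from saline tissue 2 days after the last dose, with 2 arrays against 1. The lists of cell division rose and the lists of parietal cells and of mitochondrial metabolism fell. All 42 G2/M genes were higher, with a median of 0.80, among them Mki67 at 1.71 ± 0.13, the kinetochore motor Cenpe at 1.45 ± 0.17 and the topoisomerase Top2a at 1.39 ± 0.28. All 37 G1/S genes were higher, with a median of 0.59, among them Hells at 1.89 ± 0.25, Rrm2 at 1.50 ± 0.34 and the DNA ligase gene Lig1 at 1.20 ± 0.13. In camera the adjusted p was 5.37e-19 for G2/M and 1.26e-17 for G1/S, and the adjusted p was 0.646 for both with an estimated correlation. In limma, adjusted over the list alone, 28 G2/M and 27 G1/S genes passed, against 0 over all genes tested.

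Of 27 parietal cell genes 22 were lower at 48 h, and the list fell, with a median of -0.90. Slc26a7 was at -4.20 ± 0.26, Aqp4 at -2.54 ± 0.47 and the growth factor gene Vegfb at -1.73 ± 0.10. Gpr155 was at -3.95, or -1.49 as the mean of its probe sets. The pump genes were at -0.91 ± 0.38 for Atp4b and -0.83 ± 0.42 for Atp4a, and the anion transporter gene Slc26a9 was at -1.13 ± 0.37. Esrrg, a nuclear receptor gene of parietal cells, was at 0.03 ± 0.24. The list's adjusted p in camera was 1.27e-05, and 6 genes passed in limma when adjusted over the list alone. With an estimated correlation the adjusted p was 0.646.

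Metabolic lists fell with it. All 21 TCA cycle genes were lower, with a median of -0.39, including the isocitrate dehydrogenase subunit gene Idh3g at -0.89 ± 0.09 and Idh2 at -0.88 ± 0.13. Of 64 oxidative phosphorylation genes 58 were lower, with a median of -0.27, including the complex I gene Ndufs1 at -0.77 ± 0.08. Cholesterol synthesis genes had a median of -0.54, including Insig1, which restrains sterol synthesis, at -1.11 ± 0.30 and squalene synthase Fdft1 at -0.97 ± 0.22. The adjusted p in camera was 1.89e-08 for the TCA cycle, 7.97e-08 for oxidative phosphorylation and 7.09e-05 for cholesterol synthesis. The adjusted p with an estimated correlation was 0.646, 0.686 and 0.646 in the same order. Adjusted over the list alone, 9, 0 and 2 of their genes passed in limma.

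The endothelial list fell too, with a median of -0.52 and 11 of 14 genes lower, including endomucin (Emcn) at -1.61 ± 0.12, the VEGF receptor gene Kdr at -1.53 ± 0.26 and Plvap at -1.35 ± 0.16. Its adjusted p in camera was 6.75e-05, and 9 genes passed in limma when adjusted over the list alone. Once the correlation was estimated, the adjusted p was 0.646. The list was already at -0.47 at 24 h and -0.48 at 36 h, against -0.45 and -0.61 on the 48 h arrays. Emcn, Kdr and Plvap lay below the control by a near-constant size on all 6 toxin arrays. A trait of the lone control array is therefore not separated from a response to the toxin for these genes. The interferon list rose, with 35 of 39 genes higher and a median of 0.54, including Oas2 at 2.12 ± 0.56 and Irf7 at 1.13 ± 0.45. Its median was 0.94 on the first 48 h array and 0.26 on the second, where it was 0.17 with quantile normalisation again and 0.12 with array medians subtracted. The ribosomal protein list rose as well, with 51 of 63 higher and a median of 0.33; their medians of 0.25 and 0.40 on the 2 arrays were 0.15 and 0.26 with array medians subtracted. Camera gave an adjusted p of 4.41e-06 for interferon and 1.83e-08 for ribosomal proteins. With an estimated correlation the adjusted p was 0.686 and 0.646, and adjusted over the list alone, no interferon gene and 7 ribosomal protein genes (6 higher, 1 lower) passed in limma.

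Further lists passed camera at 48 h with smaller shifts. The chief cell list fell, with a median of -0.37, including the lactate transporter gene Slc16a7 at -1.93 ± 0.30 and Bhlha15, a regulator of secretory cells, at -0.83 ± 0.20, while pepsinogen C (Pgc) was at -0.03 ± 0.05. The adjusted p was 0.0124. The unfolded protein response list fell, with a median of -0.25, including Chac1 at -1.32 ± 0.20 and Herpud1 at -1.02 ± 0.28, with an adjusted p of 0.00789. Fatty acid oxidation fell, with a median of -0.33 and an adjusted p of 0.00790, including the medium-chain dehydrogenase gene Acadm at -0.89 ± 0.13. Glycolysis fell, with a median of -0.11 and an adjusted p of 0.0150, including Pfkfb3 at -1.86 ± 0.28. The hypoxia list had a median of -0.33 and an adjusted p of 0.0448, with the carbonic anhydrase gene Car9 at -1.63 ± 0.24, and p53 targets had a median of -0.08 and an adjusted p of 0.0472. The immediate early list rose, with a median of 0.20 and an adjusted p of 0.0159, including the transcription factor genes Egr1 at 1.34 ± 0.22 and Atf3 at 1.07 ± 0.13. Tuft cell genes had a median of 0.23 and an adjusted p of 0.0254, and neutrophil genes 0.17 and 0.0150. The adjusted p with an estimated correlation was 0.646 or 0.686 for each of these 9 lists. In limma, adjusted over the list alone, 4 chief cell, 7 unfolded protein response (1 higher, 6 lower), 1 fatty acid oxidation, 3 glycolysis, 4 immediate early and 1 tuft cell genes and no neutrophil, p53 or hypoxia genes passed.

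The calls of those 9 lists depended on single arrays or on scaling. Without the first 48 h array the adjusted p in camera was 0.273 for chief cell and for immediate early genes, 0.104 for p53 targets and 0.0647 for the unfolded protein response. Without the second it was 0.222 for tuft cell, 0.251 for glycolysis, 0.0547 for fatty acid oxidation, 0.0517 for neutrophil, 0.0555 for p53 targets and 0.345 for hypoxia. Quantile normalisation of the arrays again ended the calls of tuft cell, glycolysis, fatty acid oxidation, neutrophil, p53, unfolded protein response and hypoxia, with adjusted p from 0.0506 to 0.134. With dim genes left out the adjusted p was 0.0702 for tuft cell, 0.0630 for glycolysis and 0.117 for p53 targets and hypoxia, and the neutrophil list was too short to test. With array medians subtracted, list medians on the 2 arrays of 48 h went from -0.05 and -0.15 to -0.15 and -0.29 for glycolysis, from -0.09 and -0.16 to -0.19 and -0.30 for p53 targets and from 0.14 and 0.19 to 0.05 and 0.04 for neutrophil genes. The median of the tuft cell list turned negative on the first 48 h array with either scaling, and that of immediate early genes on the second with array medians subtracted.

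No single gene passed in the 48 h comparison: limma called 0 of 22180 genes, the smallest adjusted p was 0.120, and 4375 genes had an unadjusted p under 0.05 (1810 higher, 2565 lower), where 1109 would by chance. The count differed in other settings, with 7 genes called after quantile normalisation again, 167 with array medians subtracted and 143 among genes with at least 6 distinct values. The largest values without overlap between the arrays were Dmbt1 at 3.69 ± 0.34 and Clca1 at 3.39 ± 0.29 among higher genes, beside the Y-linked genes Eif2s3y at 4.34 ± 0.14, Uty at 4.03 ± 0.15 and Kdm5d at 3.25 ± 0.28. Lower genes were B4galnt2 at -5.63 ± 0.14, Xist at -4.98 ± 0.13, Rnase1 at -4.52 ± 0.44 and Hamp2 at -4.23 ± 0.56. The mucous neck cell list, with 7 of 10 genes higher, and the metaplasia list, with 11 of 19 higher, did not pass camera (adjusted p 0.240 and 0.355). Their genes went both ways, with Gkn3 at 1.31 ± 0.49 and the chloride channel gene Cftr at 1.62 ± 0.78, but the mucin glycosylation genes A4gnt at -0.70 ± 0.54 and Galnt6 at -0.59 ± 0.24. The secreted chaperone gene Clu was at 0.71 ± 0.06 and Muc5ac, the main surface mucin, at 0.48 ± 0.09. The antimicrobial lectin gene Reg3g was at 1.88 ± 0.38 and the gastrin gene Gast at 1.17 ± 0.47, while the somatostatin gene Sst was at -0.95 ± 0.29. Both 48 h arrays lay on the same side of the control in 14713 genes (66.3%), where chance gives 66.7% for values without ties. Ties with the control did not count as the same side, so the chance share here was lower, and it was not computed.

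The comparison of 72 h with the control asked what still differed 3 days after the last dose, again with 2 arrays against 1. The cell division lists still rose, by smaller medians, and the parietal cell list still fell. The G2/M list had 42 of 42 genes higher and a median of 0.43, including Mki67 at 1.01 ± 0.13 and the mitotic cyclin gene Ccnb2 at 0.91 ± 0.19. The G1/S list had 36 of 37 genes higher and a median of 0.34, including Hells at 1.38 ± 0.25 and the replication helicase gene Mcm5 at 0.78 ± 0.07. In camera the adjusted p was 3.61e-10 for G2/M and 3.02e-10 for G1/S, and with an estimated correlation the adjusted p was 0.925 for both. Adjusted over the list alone, 1 and 9 genes passed in limma, against 0 over all genes tested.

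The parietal cell list was divided at 72 h, with 20 of 27 genes lower and a median of -0.46. The pump genes Atp4b at -0.15 ± 0.38 and Atp4a at -0.25 ± 0.42 and the potassium channel subunit gene Kcne2 at -0.27 ± 0.32 were within their errors of the control. Slc26a7 was at -3.55 ± 0.26, the potassium channel gene Kcnj16 at -1.35 ± 0.38 and the nuclear receptor gene Esrrb at -1.29 ± 0.24. Gpr155 was at -3.53 ± 0.33 on the probe set used and at -1.30 as the mean of its probe sets. The adjusted p in camera was 0.0113 for the list, and 3 genes passed in limma when adjusted over the list alone. Once the correlation was estimated, the adjusted p was 0.925, without the first 72 h array it was 0.103, and with dim genes left out it was 0.0620.

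The interferon list rose at 72 h, with 34 of 39 higher and a median of 0.80, including Oas2 at 2.89 ± 0.56, Ifit1 at 2.79 ± 0.94 and the deconjugating enzyme gene Usp18 at 2.11 ± 0.65. The ribosomal protein list rose, with 56 of 63 higher and a median of 0.42, including Rps28 at 1.29 ± 0.09. The endothelial list fell, with 11 of 14 genes lower and a median of -0.34, including Kdr at -1.31 ± 0.26, Emcn at -1.25 ± 0.12 and the cadherin gene Cdh5 at -0.84 ± 0.08. The adjusted p in camera was 5.17e-08, 3.61e-10 and 0.000243 for these 3 lists. With an estimated correlation the adjusted p was 0.925 for each, and adjusted over the list alone, 0, 10 (9 higher, 1 lower) and 7 of their genes passed in limma. The metabolic lists did not pass at 72 h: oxidative phosphorylation had a median of 0.13, the TCA cycle -0.08 and cholesterol synthesis -0.02, where the mean and the test pointed up. With array medians subtracted, oxidative phosphorylation turned negative on the first 72 h array and the TCA cycle on the second.

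The chief cell list fell at 72 h, with a median of -0.50, including the pepsinogen gene Pga5 at -2.75 ± 1.23, the estrogen receptor gene Gper1 at -1.27 ± 0.05 and Cblif at -1.10 ± 0.11, beside Gkn3 at 1.64 ± 0.49. The immediate early list rose, with a median of 0.29, including Egr1 at 1.21 ± 0.22. Tuft cell genes had a median of 0.22, including Sh2d6 at 0.77 ± 0.21 and the leukotriene synthase gene Ltc4s at 0.74 ± 0.06, and neutrophil genes had a median of 0.16. Camera gave an adjusted p of 0.0166 for chief cell, 0.0113 for immediate early, 0.0237 for tuft cell and 0.0224 for neutrophil genes, and with an estimated correlation the adjusted p was 0.925 for each. In limma, adjusted over the list alone, 5, 1, 1 and 0 of their genes passed. Without the first 72 h array the adjusted p was 0.0557, 0.0662, 0.103 and 0.103 in the same order, and with replicate number as a block the neutrophil list reached 0.0642. With dim genes left out the tuft cell list reached 0.0779 and the neutrophil list was too short to test.

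As single genes, limma called 0 of 22180 at 72 h, the smallest adjusted p was 0.146, and 3978 genes had an unadjusted p under 0.05 (1759 higher, 2219 lower). With the same alternatives as at 48 h it called 5, 30 and 52 genes. The largest values without overlap were Zg16 at 4.72 ± 1.21, Fcgbp at 4.19 ± 1.28 and Clca1 at 3.66 ± 0.29 among higher genes, and B4galnt2 at -5.44 ± 0.14, Xist at -5.39 ± 0.13 and Rnase1 at -3.87 ± 0.44 among lower ones. Eif2s3y was at 4.10 ± 0.14 and Uty at 3.84 ± 0.15. The spasmolytic polypeptide gene Tff2 was at 0.79 ± 0.13, the secreted inhibitor gene Wfdc2 at 0.81 ± 0.21 and Gast at 2.13 ± 0.47, with Sst at -0.64 ± 0.29. Vegfb was at -1.17 ± 0.10. Both 72 h arrays lay on the same side of the control in 15101 genes (68.1%), where chance gives 66.7% for values without ties. As at 48 h, ties with the control lower the chance share, which was not computed.

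The comparison of 72 h with 48 h asked what changed during recovery, with 2 arrays on each side and the same sex pattern on all 4. Between these times the lists of parietal cell genes, mitochondrial metabolism and cholesterol synthesis rose and the lists of cell division fell. Oxidative phosphorylation genes were higher at 72 h in 63 of 64 cases, with a median of 0.40, including the ATP synthase gene Atp5l at 0.87 ± 0.06 and the cytochrome oxidase gene Cox4i1 at 0.86 ± 0.26. All 21 TCA cycle genes were higher, with a median of 0.31, including the succinate dehydrogenase genes Sdhb at 0.62 ± 0.09 and Sdhc at 0.52 ± 0.10. All 17 cholesterol synthesis genes were higher, with a median of 0.45, including Fdps at 0.89 ± 0.09, the squalene epoxidase gene Sqle at 0.75 ± 0.06 and Cyp51 at 0.76 ± 0.16. In camera the adjusted p was 7.70e-25, 1.68e-12 and 4.98e-11 for these 3 lists, and with an estimated correlation the adjusted p was 0.952 for each. Adjusted over the list alone, 4, 0 and 2 of their genes passed in limma.

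Of 27 parietal cell genes 21 were higher at 72 h than at 48 h, with a median of 0.51, including Aqp4 at 1.43 ± 0.38, the creatine kinase gene Ckb at 1.18 ± 0.25 and the anion exchanger gene Slc4a2 at 1.11 ± 0.32. Atp4b was at 0.76 ± 0.31, Atp4a at 0.58 ± 0.34 and Kcne2 at 0.57 ± 0.26. The adjusted p in camera was 6.60e-05, with no gene passing when adjusted over the list alone. The adjusted p with an estimated correlation was 0.965, and without the first 48 h array it was 0.111. All 42 G2/M genes were lower at 72 h, with a median of -0.38, including Cenpe at -0.77 ± 0.14, Top2a at -0.74 ± 0.23 and Mki67 at -0.70 ± 0.11. Of 37 G1/S genes 35 were lower, with a median of -0.26, including the primase gene Prim1 at -0.65 ± 0.23. The adjusted p in camera was 1.13e-15 for G2/M and 6.65e-11 for G1/S, with 1 and 0 genes passing when adjusted over the list alone. Once the correlation was estimated, the adjusted p was 0.965 and 0.952.

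Glycolysis rose by a median of 0.19, including the lactate dehydrogenase gene Ldhb at 1.13 ± 0.17. Its list also held Pigq, which is not a glycolytic gene, at 0.18, next to the median. Fatty acid oxidation rose by 0.13, including the very-long-chain dehydrogenase gene Acadvl at 0.70 ± 0.21. The unfolded protein response rose by 0.07, including Creld2 at 0.77 ± 0.23. Camera gave an adjusted p of 0.00123, 0.000711 and 0.0319, and with an estimated correlation the adjusted p was 0.965, 0.952 and 0.965. In limma, adjusted over the list alone, none of their genes passed. The glycolysis call ended without the second 48 h array (adjusted p 0.259) and without the second 72 h array (0.0636). The unfolded protein response call ended without the first 48 h array (0.217), without the first 72 h array (0.363), with the replicate block (0.0698) and with quantile normalisation again (0.235).

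**Figure D2:**
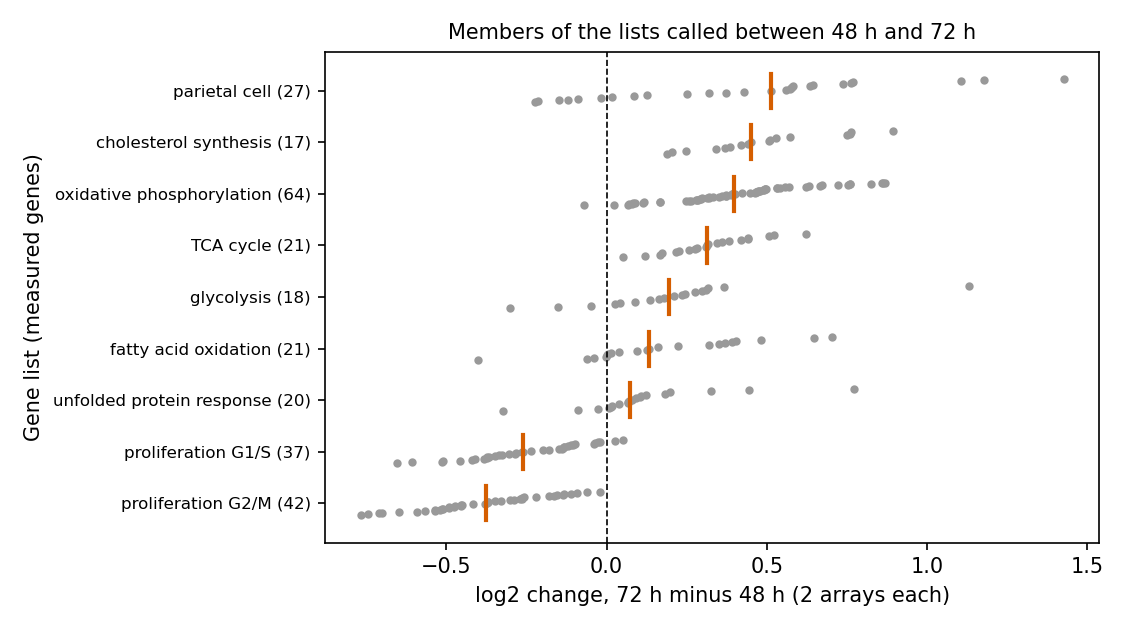
Log2 difference at 72 h minus 48 h (x axis) of the members of the 9 lists that passed camera (y axis); grey points are genes and the orange bar is the list median. Medians ran from -0.38 for G2/M to 0.51 for parietal cell genes, and 63 of 64 oxidative phosphorylation genes were above 0.

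As single genes, limma called 0 of 22180 between 72 h and 48 h, the smallest adjusted p was 0.705, and 1569 genes had an unadjusted p under 0.05 (948 higher, 621 lower) against 1109 by chance. The pairs did not overlap in 6600 genes (29.8%), where chance gives 33.3% for values without ties. Ties between the pairs counted as overlap, so the chance share here was lower, and it was not computed. Values furthest up were Zg16 at 2.62 ± 0.99, the cardiac-type troponin gene Tnni3 at 2.40 ± 0.68, Fcgbp at 2.26 ± 1.05, Apoa1, the main protein of high-density lipoprotein, at 1.97 ± 0.76 and the carbonic anhydrase gene Car3 at 1.78 ± 0.65. Values furthest down were the hepcidin gene Hamp at -3.10 ± 1.60, Reg3g at -1.22 ± 0.31, the liver enzyme gene Tat at -1.18 ± 0.63, Hrg at -1.12 ± 0.75 and Ly6c1 at -1.11 ± 0.28. Tff2 was at 0.62 ± 0.11, Gast at 0.96 ± 0.38, Vegfb at 0.56 ± 0.08 and Sox9, a progenitor transcription factor gene, at -0.51 ± 0.23.

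The time trend asked which genes rose or fell over the 6 toxin arrays from 24 h to 72 h, as a slope per 24 h. A slope does not require steady movement. Of these arrays only the 24 h array had the sex pattern of the control, so slopes may also reflect sex pattern. Cell division lists fell and parietal cell and metabolic lists rose over this time. The G2/M list had a median slope of -0.35, with all 42 slopes negative, including Top2a at -0.59 ± 0.11, Kif11, a spindle motor gene, at -0.54 ± 0.08 and Mki67 at -0.45 ± 0.10. The G1/S list had a median slope of -0.27, with 36 of 37 slopes negative, including Hells at -0.59 ± 0.12 and the polymerase gene Pola1 at -0.42 ± 0.04. In camera the adjusted p was 8.02e-35 and 5.79e-25, and with an estimated correlation the adjusted p was 0.427 for both. Adjusted over the list alone, 39 and 27 of their genes passed in limma.

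The parietal cell list rose over time, with 22 of 27 slopes positive and a median of 0.18, including Aqp4 at 0.90 ± 0.25, Atp4b at 0.83 ± 0.24, Slc4a2 at 0.78 ± 0.19, Atp4a at 0.48 ± 0.18 and Kcne2 at 0.45 ± 0.14. Oxidative phosphorylation had a median slope of 0.22 with 61 of 64 positive, the TCA cycle 0.18 with all 21 positive, glycolysis 0.12 and cholesterol synthesis 0.35 with all 17 positive. The adjusted p in camera was 2.41e-06 for parietal cell genes, 6.18e-22 for oxidative phosphorylation, 4.95e-11 for the TCA cycle, 0.000368 for glycolysis and 1.10e-06 for cholesterol synthesis. With an estimated correlation the adjusted p was 0.427 for the first 4 and 0.472 for cholesterol synthesis, whose call also ended without the 24 h array (0.0605). The macrophage list fell, with 17 of 18 slopes negative, a median of -0.11 and an adjusted p of 2.92e-05 in camera, including the perforin-like gene Mpeg1 at -0.34 ± 0.10. With an estimated correlation its adjusted p was 0.427. In the lists of this paragraph, 1 oxidative phosphorylation gene and no other passed in limma when adjusted over the list alone.

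The other 6 lists that passed camera in the trend lost the call when 1 array was left out, as cholesterol synthesis did. Antrum genes, with a median slope of 0.14 and an adjusted p of 0.0323, included Gast at 0.83 ± 0.23, and reached 0.475 without the 24 h array and 0.223 without the first 72 h array. Pancreas genes (0.10, adjusted p 0.0162) included the elastase gene Cela1 at 0.83 ± 0.22, and reached 0.167 without the 36 h array, 0.0934 without the first 72 h array and 0.120 with dim genes left out. Heat shock genes (0.08, adjusted p 0.0323) reached 0.264 without the 36 h array, 0.492 without the first 72 h array and 0.153 with quantile normalisation again. Tuft cell genes (0.07, adjusted p 0.0414) reached 0.493 without the 24 h array, 0.0608 without the first 48 h array and 0.0750 without the first 72 h array. Fatty acid oxidation (0.08, adjusted p 0.00860) reached 0.0789 without the 24 h array and 0.0660 without the second 72 h array. Wnt and stem cell genes (-0.07, adjusted p 0.0323) reached 0.381 without the 24 h array, 0.0750 without the first 72 h array, 0.0660 without the second and 0.0618 with dim genes left out. With an estimated correlation the adjusted p in camera was 0.652 for heat shock, 0.472 for fatty acid oxidation and 0.427 for the other 4 lists. Among these 6 lists, 1 fatty acid oxidation gene, with a negative slope, passed in limma when adjusted over the list alone.

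As single genes, limma called 0 of 22180 in the trend, the smallest adjusted p was 0.380, and 1929 genes had an unadjusted p under 0.05 (937 with a positive slope, 992 with a negative one) against 1109 by chance. The largest slopes upwards were Zg16 at 1.60 ± 0.85, Fcgbp at 1.57 ± 0.94 and Tnni3 at 1.51 ± 0.40, beside Eif2s3y at 1.42 ± 0.81 and Uty at 1.37 ± 0.74. The largest downwards were Xist at -2.28 ± 0.90, Hamp at -1.01 ± 0.93, the kinetochore gene Zwilch at -0.65 ± 0.09 and the histone genes H4f16 at -0.65 ± 0.34 and H2ac1 at -0.64 ± 0.43. On the 24 h array, which shares the sex pattern of the control, Xist was at 1.04 and Eif2s3y and Uty were each at -0.41 from the control.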

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

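The tests of explanations for the interferon list, for Slc26a7 and Gpr155 and for sex as the source of the step were chosen after the results were seen.

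Between 48 h and 72 h, 9 lists differed by a test of the difference itself with camera, given here as median log2 change. Parietal cell genes differed by 0.51, oxidative phosphorylation by 0.40, cholesterol synthesis by 0.45, the TCA cycle by 0.31, glycolysis by 0.19, fatty acid oxidation by 0.13 and the unfolded protein response by 0.074. G2/M genes differed by -0.38 and G1/S genes by -0.26. The smallest adjusted p in camera with an estimated correlation was 0.952, and without the first 48 h array the parietal cell list reached 0.111 and the unfolded protein response 0.217. Glycolysis reached 0.259 without the second 48 h array and 0.0636 without the second 72 h array, and the unfolded protein response 0.363 without the first 72 h array.

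Among named genes, 5 lay on opposite sides of the control at 48 h and 72 h on every array; that they lay on opposite sides was not tested, and limma called no gene between the times. Hamp differed by -3.10 between 72 h and 48 h, Tat by -1.18, Hrg by -1.12 and Sox9 by -0.51, and Tnni3 by 2.40. The 2 arrays of 48 h differed in Hamp, at 0.53 and 4.54 from the control, Hrg, at 0.02 and 1.89, and Tat, at 0.11 and 1.69.

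Signal outside the named genes also differed from the control. Of 16010 probe sets with no gene, 96 were at least 2-fold above the control on all 6 toxin arrays and 19 at least 2-fold below. Of 1814 probe sets with several genes the counts were 2 and 4, and of the 22180 tested genes 27 and 119. The median probe set with no gene lay 0.04 above the control, and the median tested gene at 0. These counts were not repeated with array medians subtracted. Simulated unchanged genes measured against the same lone control gave 2 above and 6 below out of 22180. Their noise was independent and sized by the 48 h and 72 h pairs of the tested genes. The simulation therefore does not cover a trait of the control array or the noise of probe sets outside the tested genes.

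The interferon list was higher on all 6 toxin arrays, by medians from 0.26 to 0.94, or from 0.12 to 0.89 with array medians subtracted. A difference in sex pattern is argued against by the 24 h array, which shares the control's pattern and had a median of 0.756. More macrophages as the whole source is argued against by their list, whose median over the 6 arrays was 0.0116. Its 5 most abundant genes were Lyz2 at 0.70, Csf1r at -0.21, Mrc1 at -0.25, C1qb at -0.01 and Cd68 at 0.03. The macrophage list was at 0.19 at 24 h and 0.14 at 36 h, both above the bounds of the random lists. With array medians subtracted these were 0.11 and 0.04. On the 48 h and 72 h arrays it lay between -0.01 and 0.02. More macrophages as a part of the rise at 24 h and 36 h therefore stay open. More neutrophils stay open too, since their list was at 0.144 (0.11 to 0.19, or 0.03 to 0.10 with array medians subtracted). That list is made of dim genes, with a control median of 3.89, below the 5.16 of all genes. The state of the control animal cannot be told apart from a response to the toxin, since there is 1 control: the mean at 72 h exceeded that at 48 h by 0.253, within the pooled SD of the pairs of 0.35, so the list showed no return to the control. An interferon response in the recovering tissue may remain as a hypothesis, as may a change in the state of the immune cells present, which was not tested.

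Slc26a7 and Gpr155 stayed low at 72 h while Atp4a and Atp4b were near the control. A lower share of parietal cells alone would lower all 4 genes alike, but the smallest gap below the mean of Atp4a and Atp4b on a 72 h array was -3.06. For Gpr155 the size depends on the probe set, as the mean of its probe sets was at -1.30 at 72 h, while Slc26a7 has 1 probe set. Sex of the mice is argued against by the 24 h array, where the smaller of the 2 differences was -3.72. Slower return of some parietal cell genes in new cells may be the source, while a trait of the lone control animal or of its genetic background stays open: Slc26a7 has another gene with a constant step, Tmem64, within 10 genes on its chromosome, and Gpr155 has none.

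A step between the control and all 6 toxin arrays, of at least 2-fold and with a range over the arrays of at most 50% of its mean, was seen in 104 genes, 11 higher and 93 lower, led by B4galnt2 at -5.60 and Rnase1 at -4.28. Sex is argued against as the source: of 118 genes with such a step on the 5 later arrays, chosen without the 24 h array, 114 went the same way at 24 h, with a median of 1.49, and the 4 that did not were Xist, Eif2s3y, Uty and Kdm5d. Linked differences in genetic background cannot be told apart from the rest: 10 step genes had another within 10 genes on the chromosome, where random sets gave a median of 9 and 47.8% gave as many, a count that would miss scattered variants. The step genes included Emcn, Kdr and Plvap of the endothelial list and Slc26a7, Gpr155, Vegfb, Kcnj16 and Esrrb of the parietal cell list. Pfkfb3, Chac1 and Gper1, named above with the glycolysis, unfolded protein response and chief cell lists, were step genes too. For all step genes a trait of the lone control and a response to the toxin both stay open and were not separated. Near-constant size over 24 h to 72 h while Atp4b returned may make some of these genes, B4galnt2 among them, a candidate for follow-up with more control animals.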

How the results depend on the processing

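The alternatives with at least 6 distinct values, crossed replicate numbers, without genes of X and Y, fry, and the list trend without the 24 h or 36 h array were chosen after seeing the data. At 48 h against control limma called 7 genes (2 higher, 5 lower) with quantile normalisation again, 167 (20, 147) with array medians subtracted and 143 (35, 108) among genes with at least 6 distinct values, against 0 as reported. At 72 h against control the counts were 5 (2, 3), 30 (4, 26) and 52 (11, 41). The prior degrees of freedom rose from 1.15 to 2.10, 2.69 and 3.18 in these fits; the cause of the added calls was not tested. Subtracting array medians moved the median of all genes by -0.14 on the second 48 h array. Every other setting that kept both arrays of the toxin group gave 0 calls in these comparisons. For 72 h against 48 h and the trend, every setting that was run gave 0. With all probe sets, 1832 (1201, 631) differed 2-fold at 24 h and 2129 (1537, 592) at 36 h, out of 41345 probe sets. Of lists, an estimated correlation and fry each called 0 in all 4 comparisons (smallest adjusted p with fry 0.125, 0.0682, 0.418 and 0.175). With an estimated correlation camera had only 2 residual degrees of freedom in the group fit and 4 in the trend, so its lack of calls decides little. In that test oxidative phosphorylation, with 63 of 64 genes higher at 72 h than at 48 h, had an unadjusted p of 0.143. Its genes were measured on the same arrays and are not independent replicates, and fry gave the list an adjusted p of 0.418. Quantile normalisation again left 11 list calls at 48 h against 18; the causes of these list losses were not tested. Leaving out single arrays gave 13 to 14 list calls at 48 h, 7 to 12 at 72 h, 9 to 12 between them and 12 to 15 in the trend. Without genes of X and Y no list call was lost in any comparison. The parietal cell medians moved by less than the spread of the pairs under both scalings. Of 300 values of named genes 11 changed sign with quantile normalisation again, 17 with array medians subtracted and 0 with the mean of a gene's probe sets. Of genes above the median signal of all probe sets 47.3% had distinct values on all 7 arrays, and of dimmer genes 28.7%, so ties were more frequent in dim genes and present in both.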

Other observations

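The tests of this part on clock genes were chosen after the results were seen, and so were the counts of lists over the time orders; the count of genes over those orders was written before.

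Several further genes differed from the control on every toxin array; they are given as single genes and not as a tested group, and some were chosen after their values were seen. The cytochrome P450 gene Cyp2b10 ranged from 1.19 on the first 48 h array to 2.51 at 36 h, the glutathione transferase gene Gstm3 was at 2.22 at 24 h and 2.78 at 36 h, and the aldo-keto reductase gene Akr1b8 was at 1.51 and 2.04. Pigr was at 3.02 at 24 h and at 2.56 and 1.92 at 72 h, Bpifb1 at 1.22 at 24 h and at 1.43 and 1.55 at 72 h, and Clca1 at 2.32 and 3.85 at 24 h and 36 h. The vacuolar proton pump gene Atp6v0d2 was at 2.40 at 24 h and at 2.30 and 1.55 at 72 h. The lipoprotein lipase gene Lpl was at -3.12 at 24 h and the fatty acid transporter gene Cd36 at -2.55, and at 72 h they were at -3.05 and -1.97 and at -3.06 and -2.72. The growth factor gene Egf was between -2.81 and -3.21 on all 6 arrays and the fucosyltransferase gene Fut9 between -2.18 and -3.26. The pancreatic lipase gene Cel was at -2.14 at 24 h and at -1.95 and -2.39 at 72 h.

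Other genes varied between arrays without following the time. The goblet-type mucus genes Zg16 and Fcgbp were near the control at 24 h (0.26 and -0.52), at 4.93 at 36 h, at 3.34 and 3.24 on the first 48 h array, at 0.87 and 0.61 on the second, and above 4 on both 72 h arrays. The squamous keratin gene Krt4 was at -3.58 and -0.04 on the 2 arrays of 48 h and at 0.72 and -3.67 on those of 72 h, and Krtdap followed it with -3.31, 0.59, 0.74 and -3.20. On the second 48 h array Hamp was at 4.54, Hrg at 1.89, Tat at 1.69 and Cyp2e1 at 2.48, 4 genes picked for their values there, and Cyp2e1 was also at 2.59 at 36 h. The histone gene H4f16 was at 2.47 at 24 h, or 1.42 as the mean of its probe sets, and Prnd was at -4.17 at 24 h, or -2.05 as the mean of its probe sets.

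Lists that did not pass in camera at 48 h or 72 h against the control are given as medians at those times; some of them passed in the trend. Among epithelial lists, mucous neck cell genes were at 0.15 and 0.10, pit cell genes at 0.00 and -0.02, metaplasia genes at 0.37 and 0.17, with the mucin gene Muc4 at 0.95 ± 0.36 at 48 h (list medians on the 2 arrays of 48 h 0.32 and 0.00, the second at -0.14 with array medians subtracted), and enteroendocrine genes at -0.04 and -0.02, with the granin gene Chgb at 1.39 ± 0.19 and 1.62 ± 0.19. Regulators around the nuclear receptors ERR and PGC-1 were at 0.00 and -0.02, with Perm1 at -1.65 ± 0.14 at 48 h. Acute epithelial inflammation was at 0.06 and 0.11, and both 48 h arrays turned negative with either scaling. Among immune and stromal lists, MHC II genes were at 0.14 and 0.09, macrophage genes at -0.01 and 0.00, T and NK cell genes at -0.02 and -0.01, B and plasma cell genes at 0.09 and 0.01, and eosinophil and mast cell genes at 0.06 and 0.11, with Kit at -1.52 ± 0.23 at 48 h. Fibroblast genes were at -0.26 and -0.21, smooth muscle at -0.11 and -0.04, enteric neuron and glia at -0.03 and -0.09 and adipose tissue at -0.14 and 0.03.

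Markers of neighbouring tissues did not pass in camera at 48 h or 72 h. Pancreas genes were at -0.16 and -0.05, antrum genes at 0.05 and 0.17, forestomach squamous genes at -0.02 and -0.09, and intestine genes at 0.13 and 0.00 with means of -0.34 and -0.15, where Apoa4 was at -2.36 ± 0.31 at 48 h. The forestomach list differed in sign between its median and camera at both times, and the intestine list between its mean and camera at 48 h. Median, mean and camera also differed in sign for the EGFR list at both times and for macrophage, ERR, T and NK cell and Wnt lists at 48 h. At 72 h they differed for pit cell, enteroendocrine and clock lists. On single arrays the forestomach list was at -0.25 and 0.29 at 48 h and at 0.49 and -0.31 at 72 h, each outside the bounds of the random lists, so its medians per time average arrays that went opposite ways. Heat shock genes were at 0.05 and 0.20, EGFR ligands and growth factors at 0.00 and 0.15, with Bmp4 at -0.98 ± 0.23 at 48 h, and Wnt and stem cell genes at -0.01 and -0.05, with the stem cell marker Lgr5 at -0.79 ± 0.13 at 72 h. At 72 h the glycolysis, fatty acid oxidation, p53, unfolded protein response and hypoxia lists did not pass in camera.

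Clock output genes had medians of -0.09 and 0.00 at 48 h and 72 h, and Per1 was at -1.15 ± 0.19 at 72 h. Harvest at another time of day could move the 2 sides of the clock apart. On the 36 h array the median of 9 Per-side genes exceeded that of 5 Bmal1-side genes by 0.550, outside the -0.23 to 0.17 of the other toxin arrays, a pattern consistent with a different clock phase of that array. Since 36 h is the 1 time that is no multiple of 24 h from 24, 48 and 72 h, its differences from the other times may include time of day, which 1 array does not separate from recovery time.

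Chance was not excluded for the number of genes with a time trend: 5 of 100 orders of the times over the 6 toxin arrays, the real one included, gave as many genes at an unadjusted p under 0.05, with 1929 for the real order and 2216 for the highest other. As many lists as the 14 called were reached in 25 of 100 orders, with 19 in the highest other. The best list of an order had as small a p in camera as the best list of the real order, G2/M, in 2 of 100 orders, the real one included.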
